A study of Escherichia coli str. K-12 substr. MG1655 with 36 samples.

How the data were processed

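Gene counts of 36 libraries from Escherichia coli K-12 MG1655 were used, 3 culture replicates in each of 12 groups made of 4 conditions and 3 library types. Per the labels, the library types were directional total RNA sequencing, Cappable-Seq with capture of capped 5′ ends, and the capped libraries without capture. Libraries of different types with the same replicate number came from the same culture, per the labels. The deposited table holds whole-number counts of reads for 4464 genes by locus tag, which the authors made, and no scaling was found in it. The tools named by the submitters' processing notes are Bowtie2 and Salmon. Their versions, the strand setting, the treatment of reads that match several places and the genome build are not given in the sources used here. Reads of near-identical genes, such as tufA and tufB, gadA and gadB, or ydfK and ynaE, can be split between them by such counting, so values of those genes are uncertain. Columns were matched to samples by name, and 2 columns that match no sample were not used. The control columns carry a letter that the labels do not spell out, and were matched as the condition left after the drug names. Gene symbols came from a RefSeq gene table of assembly ASM584v2, which matched 4462 of the locus tags and left 2 unmatched. It was used for names and for which genes neighbour each other.

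Each library type was fitted apart in R 4.3.3 with edgeR 4.0.16, with all 12 libraries in one model of group means. Genes passed edgeR's filterByExpr, libraries were scaled by TMM, and each drug was compared with the control by the quasi-likelihood test, which is two-sided. The p-values were adjusted by Benjamini-Hochberg over the genes tested, and 0.05 was the threshold for "rose" and "fell". A further model of 24 enriched and total libraries tested whether a drug's effect differed between the library types, and one of 24 enriched and non-enriched libraries compared these in control cultures. Errors of log2 fold changes are standard errors of the fit, and errors of shares are SDs over 3 libraries. Shares of counts were compared by exact permutation. Single-library shares have 95% Clopper-Pearson intervals, which cover counting error only, since reads amplified without molecular identifiers are not independent molecules. Levels are counts scaled to the size of the library (CPM), with a prior count of 2 on the log2 scale. Chi-square tests of replicate counts found no pair of libraries within sampling noise.

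The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. By that rule the text names the 12 highest and 12 lowest protein-coding genes per drug in total RNA, among those past the test with a mean of at least 50 CPM and no overlap between the 3 drug and the 3 control libraries. It names the 6 highest and 6 lowest in enriched libraries, the 5 highest and 5 lowest per test of the difference, up to 4 members of a list with the smallest adjusted p and up to 2 that did not pass, and 11 genes tied to the drugs' targets. A few of the genes so chosen are left out of the text for length. The 26 lists were ribosomal proteins, translation factors, aminoacyl-tRNA synthetases, RNA polymerase and transcription factors, DNA gyrase and topoisomerases, SOS response, DNA replication, heat shock, cold shock, general stress, acid resistance, MarA-SoxS-Rob, multidrug efflux, outer membrane proteins, envelope stress, phage shock, oxidative stress, iron uptake, flagella and chemotaxis, TCA cycle, ATP synthase, NADH dehydrogenase I, amino acid biosynthesis, nucleotide biosynthesis, toxin-antitoxin, and small and stable RNAs. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation, under which no list passed. List tests in non-enriched libraries were added beyond the design.

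Alternatives were DESeq2 1.42.0 in place of edgeR, DESeq2 size factors or library totals in place of TMM, no filter on low counts, rRNA and tRNA genes removed, only the 6 libraries compared, each replicate left out in turn, and the replicate number as a block. For correlations they were Spearman's coefficient, genes of at least 10 CPM, and a prior count of 0.5. Library totals were not run for the tests of the difference or for enriched against non-enriched libraries. Removal of all noncoding RNA genes, and calls of opposite changes made anew under the other scalings, were added after the data were seen. The replicate number pairs library types of one culture, per the labels. In the data, each library's deviations were closest to those of its own number in 11 of 12 pairs of library types within a condition, and every r was over 0.1 in 7 of 12. Between a drug and the control every r was over 0.1 in 1 of 9 comparisons, tetracycline in enriched libraries (0.140, 0.119 and 0.147). There the number may pair the libraries, but the main values come from the model without a block, and the block is an alternative.

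The fits were tested on simulated data with 200 genes changed, drawn from the control libraries' means and the fitted spread. All other genes were left unchanged, so recovery and false calls under changes as broad as those called in the data were not tested. In total RNA, 75%, 68% and 81% of 2-fold changes and 92%, 95% and 98% of 4-fold changes were recovered for novobiocin, rifampicin and tetracycline. In enriched libraries 11%, 12% and 12% of 2-fold and 71%, 69% and 68% of 4-fold changes were recovered, and in the test of the difference, simulated for tetracycline, 9% and 64%. Of the genes called, 6.18%, 4.12% and 3.76% in total RNA, 1.20%, 2.41% and 4.76% in enriched libraries and 8.75% (7 of 80) in the test of the difference had not been changed, so false calls were above 5% for novobiocin in total RNA and for the test of the difference. Of 25 lists that were left unchanged in the simulation, 0 were called by camera. Genes were drawn independently there, so this does not test the preset correlation for lists whose genes vary together. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.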

Results

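RNA of Escherichia coli K-12 MG1655 was measured in control cultures and in cultures exposed to novobiocin, rifampicin or tetracycline. Novobiocin inhibits DNA gyrase, rifampicin binds RNA polymerase and blocks the start of transcription, and tetracycline binds the small ribosomal subunit and blocks translation. Cultures grown in Luria broth at 37 °C to logarithmic phase received 100 mg per litre of novobiocin for 20 min, 50 mg per litre of rifampicin for 30 min or 20 mg per litre of tetracycline for 30 min. The exposure times differed between drugs, and the sample labels used here give no time for the control cultures. Each of 4 conditions had 3 cultures, and each culture gave 3 kinds of library, 36 in all. Total RNA libraries came from directional RNA sequencing. Enriched 5′ end libraries came from Cappable-Seq, which caps the triphosphate at the start of a primary transcript and captures it. Non-enriched libraries were capped without the capture. Total counts per library were about 8859240 to 10383400 in total RNA, 4959780 to 22061400 in enriched and 2056040 to 8930530 in non-enriched libraries. All values below are changes relative to the other genes of a library, since no added standard gives the amount of RNA per cell.

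The shares of stable RNAs in the total RNA libraries differed between conditions. The transfer-messenger RNA ssrA, which frees stalled ribosomes, took 4.56% ± 0.48 of counts in control libraries and 27.3% ± 11.7 after rifampicin (SD, n = 3 each). The rifampicin replicates stood at 25.2%, 16.7% and 39.8%, and the exact 95% Clopper-Pearson interval of the last was 39.8 to 39.8%, counting error only. The 6S RNA ssrS, which binds RNA polymerase, took 2.93% ± 0.79 in control and 12.2% ± 4.01 in rifampicin libraries. The protein-coding share was 91.4% ± 1.25 in control and 59.5% ± 15.5 in rifampicin libraries. All tRNA genes together took 0.324% ± 0.099 in control, 0.421% ± 0.022 in novobiocin, 0.576% ± 0.049 in rifampicin and 2.59% ± 0.87 in tetracycline libraries. For ssrA and tRNA under rifampicin and tetracycline the two-sided exact permutation p was 0.1 each, the smallest that 3 libraries against 3 allow, and 0.171 after Benjamini-Hochberg adjustment over 36 such shares. In enriched libraries the small RNA gcvB, a repressor of amino acid transport genes, took 30.6% ± 4.41 of control counts, and spf (Spot 42) took 6.98% ± 2.78 in control and 20.0% ± 8.98 in rifampicin libraries.

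**Figure D1:**
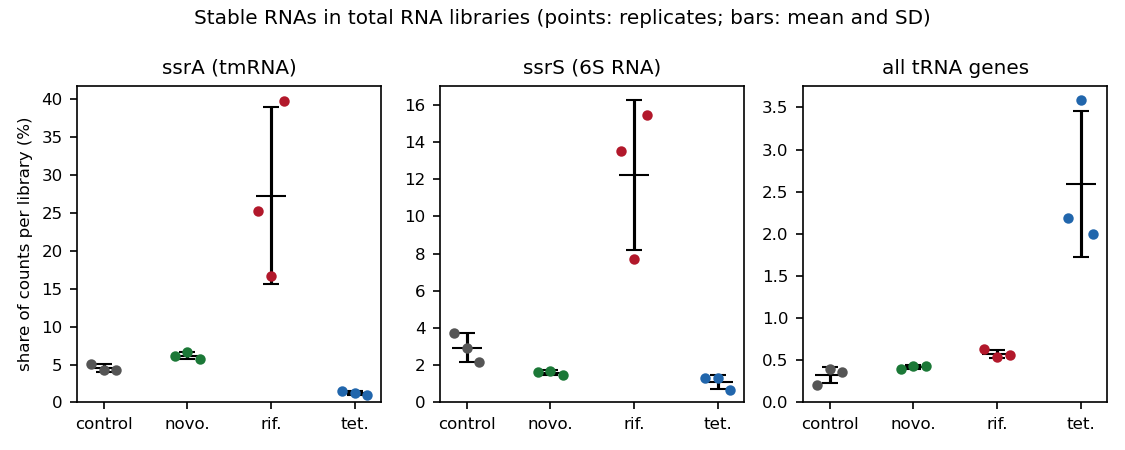
Share of counts per total RNA library (%, linear axes from 0) of ssrA, ssrS and all tRNA genes by condition, with replicates as points and the mean and SD as bars (n = 3). The rifampicin libraries lay at 16.7 to 39.8% for ssrA, and tetracycline libraries had a mean tRNA share of 2.59%.

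Novobiocin raised the genes of its target in total RNA. The gyrase subunit genes gyrA (b2231) and gyrB (b3699) rose by 2.52 ± 0.19 and 2.24 ± 0.22 on the log2 scale (SE, n = 3 against 3; adjusted p = 2.6e-08 and 3.8e-07), and topA, which encodes topoisomerase I, fell by 1.91 ± 0.15 (adjusted p = 3.8e-08). The highest genes by the naming rule were arnC (b2254, 6.35 ± 0.23), arnB (5.64 ± 0.21), arnA (5.36 ± 0.24) and arnD (4.45 ± 0.18) of aminoarabinose addition to lipid A, with eptA (4.27 ± 0.33) of phosphoethanolamine addition to lipid A. Purine synthesis genes purM (4.67 ± 0.21), purK (4.46 ± 0.26), purL (4.45 ± 0.20) and purF (4.36 ± 0.19) were also among the highest, with the hexose phosphate transporter uhpT (4.69 ± 0.30), the purine base permease ghxP (4.23 ± 0.19) and ybiE (4.56 ± 0.25). The lowest genes were the D-serine transporter dsdX (b2365, -7.44 ± 0.31), yhjX (-6.88 ± 0.57), the dihydroxyacetone kinase genes dhaL (-5.47 ± 0.33), dhaM (-5.13 ± 0.27) and dhaK (-4.40 ± 0.29), the cold shock genes cspB (-5.39 ± 0.47) and cspG (-4.79 ± 0.37), and the porin gene ompF (-4.61 ± 0.23). The tryptophan permease gene mtr (-4.10 ± 0.25), the vitamin B6 oxidase gene pdxH (-4.40 ± 0.22), ymcF (-4.40 ± 0.34) and ygeV (-4.09 ± 0.26) were also among the lowest.

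Of 17 iron uptake genes 17 fell under novobiocin, with a median of -2.82, among them fepC (-3.82 ± 0.32), fhuA (-3.65 ± 0.21) and entF (-2.66 ± 0.21) of siderophore synthesis and uptake (camera adjusted p = 5.0e-07; adjusted p = 0.34 with an estimated correlation). Of 30 amino acid biosynthesis genes 24 fell, 25 when adjusted over the list alone, as trpE (-5.73 ± 0.30), ilvC (-3.38 ± 0.16) and hisG (-3.00 ± 0.17) did (camera adjusted p = 7.1e-07; adjusted p = 0.34 with an estimated correlation). Of 21 nucleotide biosynthesis genes 15 rose and 1 fell, 15 and 2 when adjusted over the list alone (camera adjusted p = 9.3e-06; adjusted p = 0.34 with an estimated correlation). Of 10 acid resistance genes 9 rose, such as the regulator gadE (4.11 ± 0.35) and slp (2.71 ± 0.20), with a median of 2.63 (camera adjusted p = 3.7e-04; adjusted p = 0.34 with an estimated correlation). The near-identical gadA and gadB, at 3.12 ± 0.27 and 3.12 ± 0.29, can share reads. Of 11 cold shock genes 7 fell and 2 rose, and of 17 heat shock genes 11 rose and 1 fell, hslV (2.59 ± 0.19) and groS (2.40 ± 0.20) among them. Their camera adjusted p were 0.0487 and 0.00281, with adjusted p = 0.543 and 0.601 with an estimated correlation.

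In the TCA cycle list 10 of 13 rose and 1 fell under novobiocin, as sdhD (3.42 ± 0.27) and gltA (1.89 ± 0.17) did, 9 of 9 ATP synthase genes rose, such as atpB (1.23 ± 0.16), and 6 of 13 NADH dehydrogenase I genes rose. Camera gave adjusted p of 0.00133, 0.00827 and 0.0487, and adjusted p = 0.543, 0.543 and 0.670 with an estimated correlation. Of 12 translation factor genes 10 rose, prfA (2.16 ± 0.17) among them, of 23 aminoacyl-tRNA synthetase genes 15 rose and 3 fell, and of 11 RNA polymerase and transcription factor genes 8 rose and 2 fell, led by the sigma factor gene rpoD (3.02 ± 0.22). Their camera adjusted p were 0.00482, 0.0111 and 0.0111, and adjusted p = 0.543, 0.670 and 0.543 with an estimated correlation. Of 54 ribosomal protein genes 15 rose, 14 when adjusted over the list alone, rpmH (2.05 ± 0.19) among them, with a median of 0.12 that turned to -0.26 with library totals as the scaling (camera adjusted p = 0.0398; adjusted p = 0.715 with an estimated correlation). Of 18 multidrug efflux genes 9 rose, led by mdtE (4.06 ± 0.20), while acrA stood at 0.23 ± 0.17 (camera adjusted p = 0.0136; adjusted p = 0.336 with an estimated correlation).

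The remaining lists passed no set test under novobiocin. In the SOS list of DNA damage genes 10 of 19 rose and 3 fell, with recA at 1.39 ± 0.17 and uvrA at 1.75 ± 0.20, while dinB stood at -0.45 ± 0.21. Of 17 DNA replication genes 11 rose and 4 fell, of 6 gyrase and topoisomerase genes 4 rose and 2 fell, and of 15 general stress genes 7 rose and 2 fell. The general stress median of 0.21 turned to -0.18 with library totals. Of 14 MarA-SoxS-Rob genes 3 rose and 4 fell, of 9 outer membrane protein genes 1 rose and 4 fell, of 13 envelope stress genes 1 rose and 2 fell, and of 25 flagella and chemotaxis genes 5 rose and 8 fell. Of 13 oxidative stress genes 3 rose and 6 fell, sufB (-3.10 ± 0.20) among these, and the median of 0.36 had the sign opposite to the set test and turned to -0.03 with library totals. Of 6 phage shock genes 2 rose and 1 fell, 2 and 0 when adjusted over the list alone, and of 18 toxin-antitoxin genes 7 rose and 8 fell. In both lists the median, the mean and the set test differed in sign, and the toxin-antitoxin median of 0.10 turned to -0.30 with library totals. Of 13 small and stable RNAs 1 rose and 2 fell, csrB (1.28 ± 0.24) and spf (-1.92 ± 0.25) among them. For all other lists in total RNA here, counts adjusted over the list alone equalled those given.

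Of 4285 genes tested in total RNA, 2624 passed the edgeR quasi-likelihood test under novobiocin, 1286 higher and 1338 lower, and 1655 of them changed at least 2-fold. With library totals in place of TMM the median of all genes was -0.41, against -0.03, and the higher share of calls was 30.5%, against 49.0%. The direction of a small change is therefore relative to the scaling. The authors' counting settings for strand are not given in the sources used here, so overlapping and antisense genes cannot be told apart in any comparison.

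**Figure D2:**
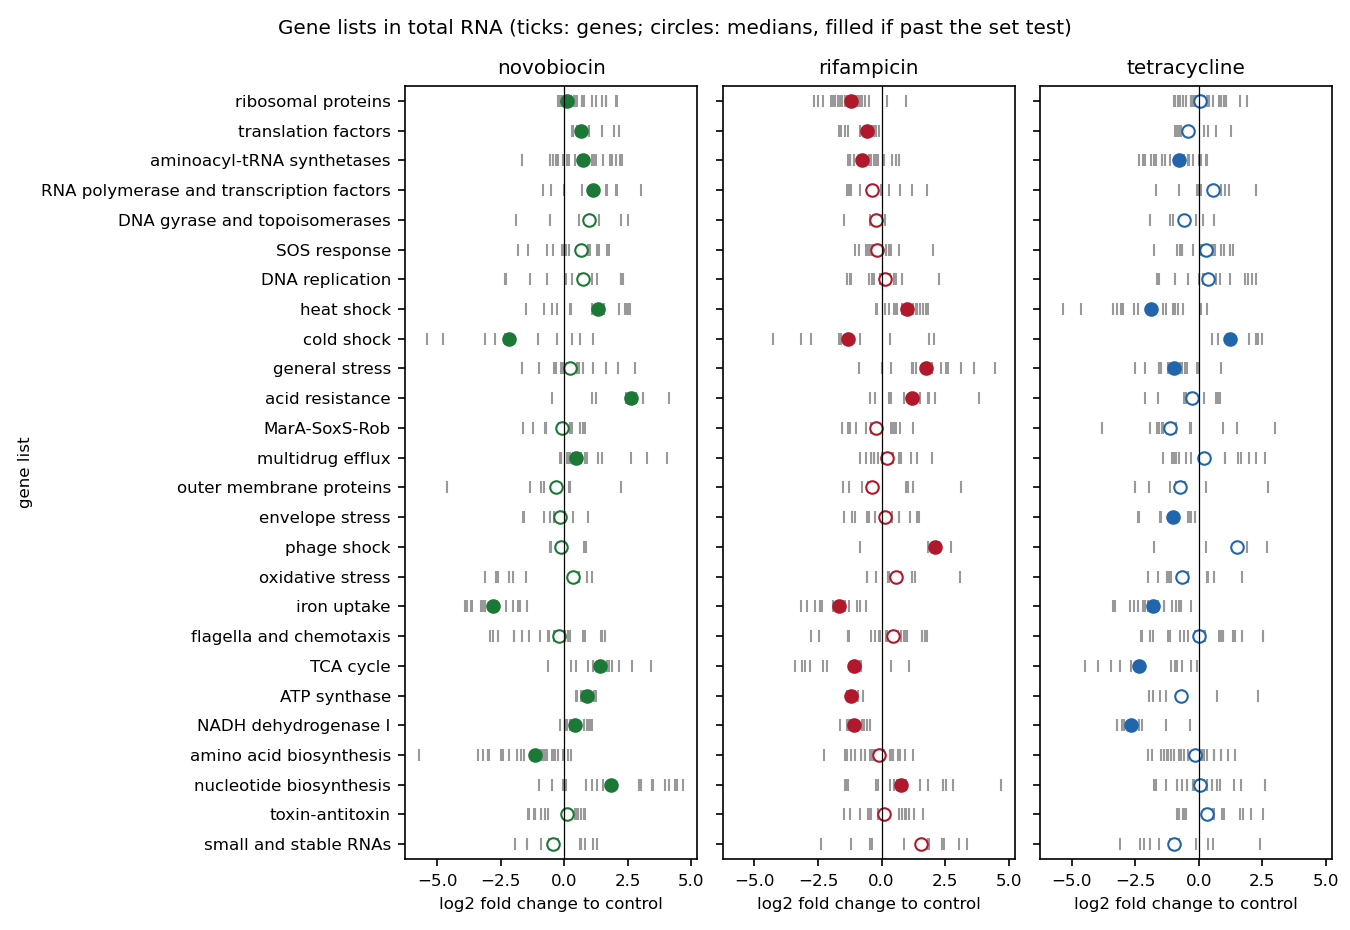
Log2 fold change to control of each gene (tick) and the median (circle) of 26 gene lists in total RNA under each drug; filled circles passed the set test with a preset correlation, and none did with an estimated one. Iron uptake medians were -2.82, -1.69 and -1.80.

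Among genes of rifampicin's target, the polymerase subunit gene rpoB stood at 0.29 ± 0.19 (adjusted p = 0.18), rpoC rose by 0.73 ± 0.20 (adjusted p = 3.9e-03) and the sigma factor gene rpoD rose by 1.77 ± 0.21 (adjusted p = 2.7e-06) in total RNA. Changes under rifampicin, here and in the lists that follow, are relative to the other genes. A rise does not by itself show new transcription, since RNA decay was not measured. The highest genes were ycaC (b0897, 5.57 ± 0.26), yjbJ (5.02 ± 0.28), the zinc-responsive regulator zntR (4.74 ± 0.26), carA of carbamoyl phosphate synthesis (4.72 ± 0.27), ugpB of glycerophosphate uptake (4.61 ± 0.21), the ribosome-associated sra (4.45 ± 0.27) and the ribosome rescue factor arfA (4.10 ± 0.23). The lowest were glpA (b2241, -6.17 ± 0.38), glpB (-5.44 ± 0.48), glpT (-6.17 ± 0.43) and glpQ (-4.67 ± 0.39) of glycerophosphate use, treB (-6.08 ± 0.41) and treC (-5.42 ± 0.39) of trehalose use, dsdX (-5.35 ± 0.27) and the maltose activator malT (-4.47 ± 0.31). The sulfate assimilation genes cysA (-4.35 ± 0.41), cysD (-4.34 ± 0.41) and cysN (-4.25 ± 0.28) followed.

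Of 54 ribosomal protein genes 52 fell under rifampicin and 1 rose, with a median of -1.20, as rpsO (-2.67 ± 0.21), rplL (-2.48 ± 0.18) and rplJ (-2.29 ± 0.18) did (camera adjusted p = 1.1e-11; adjusted p = 0.53 with an estimated correlation). ATP synthase genes fell in 9 of 9, NADH dehydrogenase I genes in 12 of 13, 13 when adjusted over the list alone, and TCA cycle genes in 11 of 13 with 1 that rose, sdhB (-3.14 ± 0.20) and sucA (-2.83 ± 0.24) among them. Camera gave adjusted p of 0.00243, 0.00104 and 0.00308, with adjusted p = 0.525 for each with an estimated correlation. Translation factor genes fell in 7 of 12, such as infB (-1.66 ± 0.18), and aminoacyl-tRNA synthetase genes in 16 of 23 with 2 that rose. Their camera adjusted p were 0.0196 and 0.0103, and adjusted p = 0.705 and 0.724 with an estimated correlation. Iron uptake genes fell in 17 of 17, median -1.69, fhuA (-3.18 ± 0.20) and fepC (-2.63 ± 0.28) among them (camera adjusted p = 2.8e-04; adjusted p = 0.525 with an estimated correlation). Cold shock genes fell in 8 of 11 with 2 that rose, cspB at -4.26 ± 0.44 (camera adjusted p = 0.0307; adjusted p = 0.525 with an estimated correlation).

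Of 15 general stress genes 12 rose and 1 fell under rifampicin, such as katE (3.63 ± 0.28) and osmC (3.14 ± 0.23), while the sigma factor gene rpoS stood at 0.02 ± 0.15 (camera adjusted p = 7.6e-04; adjusted p = 0.525 with an estimated correlation). Of 17 heat shock genes 11 rose and of 10 acid resistance genes 6 rose, gadE (3.84 ± 0.35) among these, with camera adjusted p of 0.0135 and 0.0462. Their adjusted p were 0.724 and 0.679 with an estimated correlation. Of 6 phage shock genes 5 rose and 1 fell, pspB (2.73 ± 0.25) among them (camera adjusted p = 0.0275; adjusted p = 0.525 with an estimated correlation). Of 21 nucleotide biosynthesis genes 14 rose and 3 fell, 15 and 3 when adjusted over the list alone, led by carA and by carB (2.82 ± 0.19) and pyrD (2.56 ± 0.17) (camera adjusted p = 0.0196; adjusted p = 0.525 with an estimated correlation).

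Beside these, the stable RNAs ssrA (3.05 ± 0.43), ssrS (2.46 ± 0.43) and ffs (2.38 ± 0.39), the RNA of the signal recognition particle, rose in total RNA, and csrB (-2.39 ± 0.25), which binds the regulator CsrA, fell. Of the 13 small and stable RNAs 6 rose and 2 fell. The set test was not passed by this list or by the lists that follow. Oxidative stress genes rose in 7 of 13 and fell in 2, katG at 3.08 ± 0.27, and flagella and chemotaxis genes rose in 10 of 25 and fell in 5. RNA polymerase and transcription factor genes rose in 3 of 11 and fell in 5, gyrase and topoisomerase genes fell in 2 of 6, and SOS genes rose in 2 of 19 and fell in 4, 2 and 3 when adjusted over the list alone. DNA replication genes rose in 4 of 17 and fell in 4, MarA-SoxS-Rob genes rose in 5 of 14 and fell in 6, and amino acid biosynthesis genes rose in 7 of 30 and fell in 8. Multidrug efflux genes rose in 6 of 18 and fell in 3, 6 and 2 when adjusted over the list alone, and toxin-antitoxin genes rose in 7 of 18 and fell in 6. Outer membrane protein genes rose in 4 of 9 and fell in 4, 4 and 5 when adjusted over the list alone, and their median and set test differed in sign. Envelope stress genes rose in 5 of 13 and fell in 4, 5 and 5 when adjusted over the list alone. With library totals the medians of DNA replication (-0.07), multidrug efflux (-0.05), envelope stress (-0.33) and toxin-antitoxin (-0.14) turned negative.

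Under rifampicin 2938 of 4285 genes passed, 1441 higher and 1497 lower, with 1939 changed at least 2-fold. With library totals the median of all genes was -0.19, against 0.02. The rifampicin libraries are those with the large ssrA and ssrS shares given above; removing all noncoding RNA genes, an alternative chosen after the data were seen, left 2861 genes past the test, 2815 of them shared.

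Tetracycline raised marR (3.00 ± 0.22, adjusted p = 1.4e-08) and marA (1.49 ± 0.17, adjusted p = 1.1e-06), the repressor and the activator of the multiple antibiotic resistance operon, in total RNA, while the efflux pump gene acrA stood at -0.30 ± 0.17 (adjusted p = 0.12). Of the ribosomal protein genes followed throughout, rpsJ rose by 0.57 ± 0.21 and rplC stood at 0.40 ± 0.21. The highest genes were azuC (b4663, 6.66 ± 0.46), which encodes a small membrane protein, pdeL (5.12 ± 0.25), the phosphate uptake genes pstS (31.9-fold) and pstC (16-fold), each with a log2 SE of 0.19, with their activator phoB (3.70 ± 0.22), the osmolyte transporter proP (4.68 ± 0.34), yhhQ (4.43 ± 0.19) and the manganese exporter mntP (4.38 ± 0.35). Among the lowest were sulfate assimilation genes, cysA (b2422, -6.90 ± 0.48), cysI (-6.73 ± 0.49), cysD (-6.40 ± 0.46), cysU (-6.05 ± 0.62), cysN (-6.01 ± 0.30), cysH (-5.83 ± 0.38), cysW (-5.60 ± 0.43) and cysJ (-5.48 ± 0.48). The trehalose genes treB (-6.25 ± 0.41) and treC (-5.86 ± 0.39), rbsA of ribose uptake (-5.41 ± 0.32) and glpA (-5.36 ± 0.36) were also among them.

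Heat shock and cold shock genes moved apart under tetracycline. Of 17 heat shock genes 15 fell, median -1.89, such as the chaperone genes ibpA (-5.33 ± 0.36), groS (-3.40 ± 0.21) and groL (-3.21 ± 0.21) (camera adjusted p = 1.9e-04; adjusted p = 0.758 with an estimated correlation). Of 11 cold shock genes 10 rose, median 1.24, such as the helicase gene deaD (1.96 ± 0.23) and nusA (2.24 ± 0.17), while cspB stood at 0.75 ± 0.38 (camera adjusted p = 0.00422; adjusted p = 0.583 with an estimated correlation). Of 13 NADH dehydrogenase I genes 12 fell, 13 when adjusted over the list alone, such as nuoI (-3.04 ± 0.17) and nuoH (-3.23 ± 0.19), and of 13 TCA cycle genes 11 fell, such as sucA (-4.49 ± 0.26). Camera gave adjusted p of 1.6e-06 and 2.4e-04, and adjusted p = 0.583 and 0.701 with an estimated correlation. Aminoacyl-tRNA synthetase genes fell in 17 of 23, glyS (-2.35 ± 0.17) among them, general stress genes in 12 of 15 with 1 that rose, and envelope stress genes in 10 of 13. Their camera adjusted p were 5.4e-04, 0.0281 and 0.0116, and adjusted p = 0.758, 0.758 and 0.583 with an estimated correlation. Iron uptake genes fell in 15 of 17, median -1.80, fhuA at -3.39 ± 0.20 (camera adjusted p = 3.6e-04; adjusted p = 0.708 with an estimated correlation).

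No set test passed for the other lists under tetracycline. Of 54 ribosomal protein genes 11 rose and 6 fell, 10 and 6 when adjusted over the list alone, and the median of 0.03 was -0.04 with DESeq2 size factors. Translation factor genes rose in 2 of 12 and fell in 6, and their median of -0.42 turned to 0.03 with library totals. MarA-SoxS-Rob genes fell in 9 of 14 and rose in 3, and sodA of superoxide removal stood at -3.79 ± 0.18. Multidrug efflux genes rose in 7 of 18 and fell in 6, mdfA at 2.23 ± 0.21. Outer membrane protein genes fell in 7 of 9 and rose in 1, phoE at 2.73 ± 0.23. RNA polymerase and transcription factor genes rose in 6 of 11 and fell in 2, rpoC (-1.67 ± 0.20) among these, and gyrase and topoisomerase genes fell in 3 of 6 and rose in 1. SOS genes rose in 8 of 19 and fell in 4, 7 and 4 when adjusted over the list alone, and DNA replication genes rose in 8 of 17 and fell in 4. Acid resistance genes rose in 3 of 10 and fell in 3, 2 and 3 when adjusted over the list alone, and their median of -0.27 turned to 0.12 with library totals. Amino acid biosynthesis genes rose in 7 of 30 and fell in 12, with a median that turned from -0.15 to 0.28 with library totals, and nucleotide biosynthesis genes rose in 6 of 21 and fell in 6. Phage shock genes rose in 4 of 6 and fell in 1, oxidative stress genes rose in 2 of 13 and fell in 8, and ATP synthase genes rose in 2 of 9 and fell in 7. Flagella and chemotaxis genes rose in 9 of 25 and fell in 7, with a median of 0.00 that was -0.06 with DESeq2 size factors, and toxin-antitoxin genes rose in 8 of 18 and fell in 6. Small and stable RNAs rose in 1 of 13 and fell in 6, csrB at -3.11 ± 0.25 and ssrA at -2.32 ± 0.42.

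Under tetracycline 3049 of 4285 genes passed, 1559 higher and 1490 lower, and 2027 changed at least 2-fold. With library totals the median of all genes was 0.50, against 0.08, and the higher share of calls was 68.8%, against 51.1%.

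**Figure D3:**
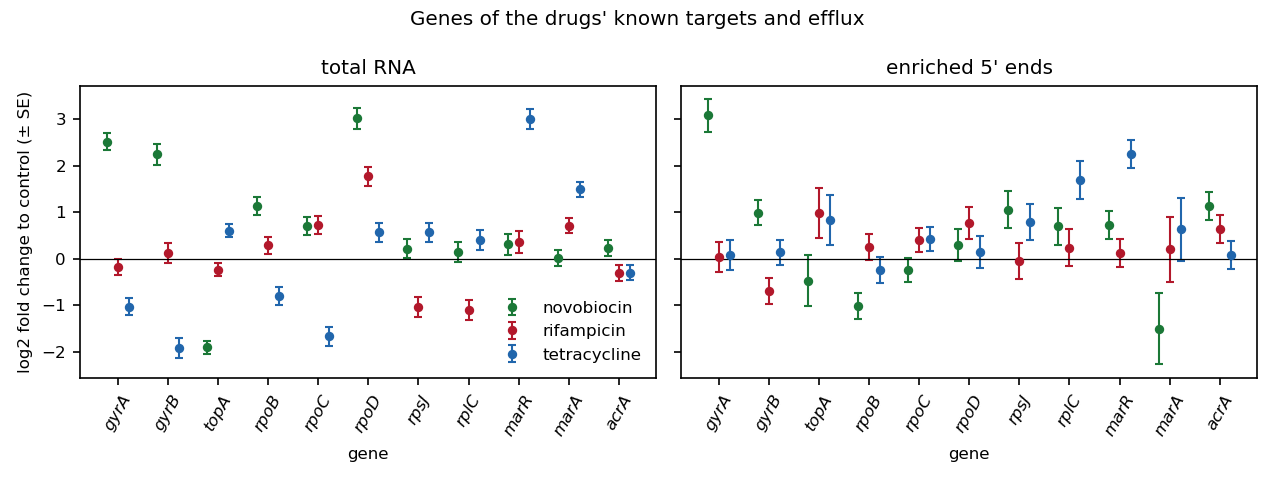
Log2 fold change to control (± SE, n = 3 against 3) of 11 genes tied to the drugs' targets and to efflux, in total RNA and in enriched 5′ end libraries, coloured by drug. In total RNA gyrA stood at 2.52 under novobiocin and marR at 3.00 under tetracycline.

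The enriched libraries asked for which genes the captured 5′ ends, counted per gene, differed. Under novobiocin gyrA rose by 3.08 ± 0.35 and gyrB by 0.99 ± 0.28 (adjusted p = 2.0e-05 and 1.2e-02), and the highest genes by the rule were purL (b2557, 4.89 ± 0.33), ybjX (4.56 ± 0.35), cvpA (4.56 ± 0.38), eptA (4.54 ± 0.37), pmrR (4.54 ± 0.41) and galF (3.89 ± 0.44). The lowest were ilvL (-3.98 ± 0.47), the leader of an isoleucine and valine operon, pdxH (-3.56 ± 0.57), metA (-3.30 ± 0.38), yihX (-3.19 ± 0.37), aroG (-3.01 ± 0.42) and mtr (-2.92 ± 0.47). Of 54 ribosomal protein genes 18 rose and 2 fell, 21 and 2 when adjusted over the list alone (camera adjusted p = 0.00105; adjusted p = 0.516 with an estimated correlation). Amino acid biosynthesis genes fell in 10 of 30 and rose in 1, 11 and 1 when adjusted over the list alone, iron uptake genes fell in 7 of 17 and cold shock genes in 5 of 10. Camera gave adjusted p of 0.0271, 0.0271 and 0.0404, and adjusted p = 0.288 for each with an estimated correlation. Of 4333 genes tested 1407 passed, 712 higher and 695 lower. Library totals put the median at -0.37, against -0.10, and the higher share at 35.7%, against 50.6%.

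Under rifampicin the highest genes in enriched libraries were ybfA (b0699, 8.57 ± 0.64), the ribosomal protein gene rplY (6.02 ± 0.60), hchA (5.50 ± 0.32), glnH of glutamine uptake (5.43 ± 0.44), ihfB (5.03 ± 0.48) and deoA (4.50 ± 0.40). The lowest were yfeC (-4.53 ± 0.65), treB (-4.38 ± 0.51), deoC (-4.35 ± 0.81), cysD (-4.14 ± 0.41) and btsS (-3.84 ± 0.47). The 6S RNA ssrS, higher in total RNA, fell by 1.67 ± 0.41 (adjusted p = 5.2e-03). General stress genes rose in 9 of 15 and fell in 1, 10 and 1 when adjusted over the list alone, wrbA (3.61 ± 0.44) and osmB (3.58 ± 0.47) among them (camera adjusted p = 0.00717; adjusted p = 0.834 with an estimated correlation). Ribosomal protein genes, most of which fell in total RNA, rose in 16 of 54 and fell in 4, 17 and 4 when adjusted over the list alone, with a median of 0.22 and no pass of the set test (camera adjusted p = 0.638). Iron uptake genes fell in 2 of 17, 1 when adjusted over the list alone (camera adjusted p = 0.583). Whether a list differed between library types was not tested. Of 4333 genes 1440 passed, 760 higher and 680 lower. Library totals put the median at 0.32, against 0.07, and the higher share at 70.6%, against 52.8%.

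Under tetracycline the highest genes in enriched libraries were azuC (6.30 ± 0.54), arfA (5.43 ± 0.53), ysgD (4.75 ± 0.46), pstS (4.71 ± 0.34), mcbR (4.35 ± 0.32) and suhB (4.17 ± 0.40). The lowest were srlA of sorbitol uptake (b2702, -5.89 ± 0.51), ygcN (-5.78 ± 0.53), malE of maltose uptake (-5.37 ± 0.51), raiA (-5.01 ± 0.49) and cysD (-4.99 ± 0.43), and marR rose by 2.26 ± 0.31. Small and stable RNAs fell in 7 of 16, 8 when adjusted over the list alone, csrB (-4.81 ± 0.48) and ssrS (-2.94 ± 0.43) among them (camera adjusted p = 0.0179; adjusted p = 0.446 with an estimated correlation). Ribosomal protein genes rose in 17 of 54 and fell in 3, 17 and 4 when adjusted over the list alone (camera adjusted p = 0.0372; adjusted p = 0.586 with an estimated correlation). Iron uptake genes fell in 2 of 17, 0 when adjusted over the list alone, and their median of -0.15 turned to 0.72 with library totals (camera adjusted p = 0.383). Of 4333 genes 1516 passed, 782 higher and 734 lower. That fit left out the replicate number, and with it as a block 1558 passed, 1465 of them shared. Library totals put the median at 0.92, against 0.07, and the higher share at 87.0%, against 51.6%. The fitted coefficient of variation between replicates was 0.355 in enriched and 0.183 in total RNA libraries, so fewer small changes could pass in enriched ones.

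Non-enriched libraries gave 2154 (1053 higher, 1101 lower), 2239 (1095 and 1144) and 2527 (1176 and 1351) of 4360 genes under novobiocin, rifampicin and tetracycline. With library totals the higher shares were 31.8%, 82.2% and 80.9%, against 48.9%, 48.9% and 46.5%, with medians of all genes at -0.46, 0.71 and 0.78. Ribosomal protein genes fell in 44 of 54 and rose in 1 under rifampicin, 46 and 1 when adjusted over the list alone, and fell in 36 and rose in 3 under tetracycline (camera adjusted p = 3.6e-08 and 0.00446; adjusted p = 0.535 and 0.751 with an estimated correlation). Under tetracycline heat shock genes fell in 16 of 17, general stress genes in 12 of 15, 13 when adjusted over the list alone, NADH dehydrogenase I genes in 13 of 13 and TCA cycle genes in 9 of 13. Camera adjusted p were 1.0e-05, 9.7e-04, 9.7e-04 and 0.00833, with adjusted p = 0.561 for each with an estimated correlation. Under rifampicin ATP synthase genes fell in 9 of 9, NADH dehydrogenase I genes in 10 of 13, 11 when adjusted over the list alone, and TCA cycle genes in 10 of 13 with 1 that rose, 10 and 2 when adjusted over the list alone. The camera adjusted p were 0.00308, 0.00308 and 0.00409, with adjusted p = 0.535 for each with an estimated correlation. General stress genes rose in 11 of 15 and fell in 3, phage shock genes rose in 5 of 6 and fell in 1, and heat shock genes rose in 7 of 17 and fell in 1, 8 and 1 when adjusted over the list alone. For these the camera adjusted p were 0.00308, 0.0142 and 0.0142, with adjusted p = 0.535, 0.535 and 0.645 with an estimated correlation.

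Novobiocin gave 10 list calls in non-enriched libraries. Nucleotide biosynthesis genes rose in 12 of 21 and fell in 3, aminoacyl-tRNA synthetase genes rose in 13 of 23 and fell in 3, 14 and 3 when adjusted over the list alone, and heat shock genes rose in 11 of 17 and fell in 2. The set tests gave camera adjusted p of 0.00164, 0.00276 and 0.00284, with adjusted p = 0.247, 0.439 and 0.439 with an estimated correlation. Acid resistance genes rose in 7 of 10 and fell in 1, TCA cycle genes rose in 8 of 13, with 1 that fell when adjusted over the list alone, and translation factor genes rose in 7 of 12. These had camera adjusted p of 0.00284, 0.00634 and 0.0246, with adjusted p = 0.439 for each with an estimated correlation. Cold shock genes fell in 9 of 11, iron uptake genes in 10 of 17 with 1 that rose, 13 and 1 when adjusted over the list alone, and amino acid biosynthesis genes in 16 of 30 with 1 that rose, 17 and 1 when adjusted over the list alone. Here camera adjusted p were 0.00276, 0.00276 and 0.00369, with adjusted p = 0.153, 0.317 and 0.247 with an estimated correlation. Flagella and chemotaxis genes, which passed no set test in total RNA, fell in 11 of 24 (camera adjusted p = 0.0186; adjusted p = 0.317 with an estimated correlation). Iron uptake genes fell in 6 of 17 under rifampicin, 5 when adjusted over the list alone, and fell in 7 and rose in 1 under tetracycline, 7 and 0 when adjusted over the list alone, and passed neither set test (camera adjusted p = 0.236 and 0.191). Their medians of -0.55 and -0.57 turned to 0.14 and 0.32 with library totals.

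In control cultures, enriched against non-enriched libraries differed in 2901 of 4404 genes, 1437 higher and 1464 lower. Counts of spf stood 13.22 ± 0.89 higher on the log2 scale in the enriched libraries (adjusted p = 3.7e-12), and lpp, the major lipoprotein gene, stood at -1.89 ± 0.45. In control non-enriched libraries spf took only 0.00104% ± 0.00062 of counts, so the size of its difference rests on few reads. For this comparison spf and lpp were named outside the rule for named genes.

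The design asks how the activity of transcription starts relates to gene expression. Across 4217 genes the Pearson r of mean levels between enriched and total RNA libraries was 0.423 in control, 0.458 in novobiocin, 0.401 in rifampicin and 0.439 in tetracycline cultures, with SDs over the 3 culture replicates of 0.008, 0.020, 0.014 and 0.005. The r of log2 fold changes was 0.457, 0.383 and 0.425 under novobiocin, rifampicin and tetracycline (jackknife SE 0.032, 0.020 and 0.018). Between total and non-enriched libraries it was 0.730, 0.712 and 0.754. Libraries of one culture share its deviations, with r of 0.181, 0.120 and 0.137 for total and enriched and 0.448, 0.197 and 0.372 for total and non-enriched libraries of the 3 control cultures, so part of each r, and of the shared directions, can come from the cultures, with no value for unchanged cultures computed, and the difference between the r is not read further. These r are across genes, which are not independent replicates, so no p is given. Among genes of at least 10 CPM in both library types the r of levels was lower, at 0.221, 0.231, 0.224 and 0.224 in the same order. Past both tests were 977, 1055 and 1124 genes, of which 863 (88.3%), 845 (80.1%) and 911 (81.0%) had the same direction. With library totals, a check added after the data were seen, genes with opposite directions numbered 72, 144 and 192, against 114, 210 and 213.

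Enriched counts are sums per gene, and the captured ends were not placed relative to gene starts here, so they are not a measure of one promoter. Under rifampicin rplY stood 7.62 ± 0.65 higher in its effect on enriched libraries than on total RNA (adjusted p = 9.7e-09), since it rose in the former and fell by 1.71 in the latter, and deoA (5.60 ± 0.43), glpQ (5.45 ± 0.50), dcuA (4.07 ± 0.38) and glpF (3.92 ± 0.42) followed. The opposite held for yjbJ (-5.95 ± 0.44, adjusted p = 1.2e-09), ugpB (-4.91 ± 0.37), agp (-4.11 ± 0.51), elbB (-3.99 ± 0.35) and rlmG (-3.33 ± 0.49). Under novobiocin dsdX (4.74 ± 0.42), the siderophore receptor gene fhuA (3.49 ± 0.30), glpA (3.47 ± 0.51), ybeL (2.47 ± 0.59) and bsmA (2.46 ± 0.64) stood higher, and argS (-3.10 ± 0.45), ybiJ (-2.99 ± 0.60), yjbJ (-2.83 ± 0.42), lgt (-2.59 ± 0.41) and rimI (-2.58 ± 0.38) lower. Under tetracycline aspA (5.41 ± 0.45), glpQ (4.79 ± 0.49), pgi (4.53 ± 0.41), ypfM (4.25 ± 0.44) and sdhB (3.76 ± 0.46) stood higher, and maa (-5.26 ± 0.40), yhhQ (-5.01 ± 0.35), pstC (-4.97 ± 0.46), ribF (-4.46 ± 0.39) and obgE (-4.24 ± 0.31) lower. In all, 1077, 1541 and 1715 of 4403 genes passed the test of the difference under novobiocin, rifampicin and tetracycline, 415, 754 and 903 of them higher in enriched libraries. That fit did not pair libraries of one culture. With the replicate number as a block 1129, 1554 and 1771 passed, 979, 1423 and 1623 of them shared. Library totals in place of TMM were not run for this test. With all noncoding RNA genes removed, an alternative chosen after the data were seen, the higher share under novobiocin was 51.7%, against 38.5%.

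**Figure D4:**
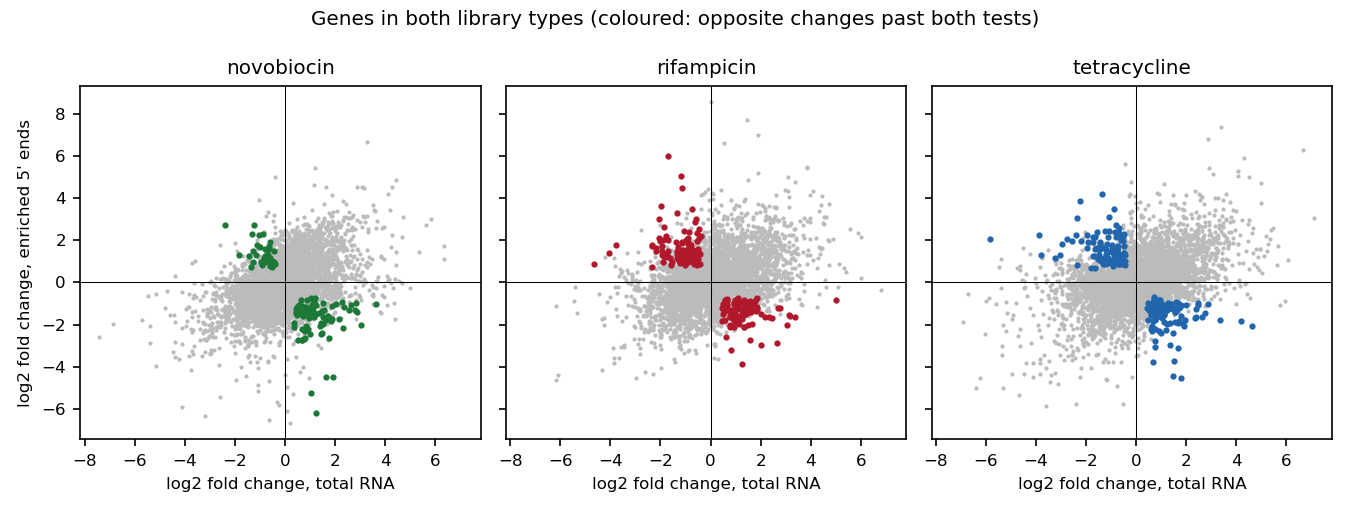
Log2 fold change to control in enriched 5′ end libraries against that in total RNA, each point 1 of 4217 genes, with a panel per drug. Coloured genes passed both tests with opposite signs: 114, 210 and 213 genes.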

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

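The tests of the difference, the other scalings and the left-out replicates were planned, and the tests of low counts and of neighbouring genes were chosen before their results were seen; the other tests, the use of scalings and left-out libraries to weigh an explanation, and the splits were chosen after the result was seen. A test of the difference between library types, the interaction of drug and library, singled out 1077 genes under novobiocin, 1541 under rifampicin and 1715 under tetracycline, whose effects in enriched 5′ end libraries and in total RNA differed. Among genes past the tests of both library types, 114, 210 and 213 changed in opposite directions. All of these passed the test of the difference too, which this choice of genes made nearly certain, so it adds no support. In non-enriched libraries the sign was that of the enriched ones in 80 of 114, 98 of 210 and 106 of 213 of these genes. Examples are rplY under rifampicin, at -1.71 in total RNA and 6.02 in enriched libraries, and maa under tetracycline, at 1.51 and -3.73.

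For these opposite changes the scaling of the library types stays open as a part of the cause, since with all genes called anew under library totals 72, 144 and 192 had opposite calls, the lowest at 63.2% of the number with TMM, and 49, 118 and 74 of them were the same genes. DESeq2 size factors gave 115, 209 and 228, with 108, 207 and 199 the same. Low counts in enriched libraries stay open too, since opposite changes made up 11.9% of genes past both tests at 50 CPM or more (93 of 783), against 17.0% of all (537 of 3156). Ends of a neighbouring gene may contribute: summed over the 3 drugs, 24.3% of the neighbours of genes with opposite changes (184 of 756) and 22.2% of those of genes with equal directions (841 of 3785) changed against the gene's own total RNA, a difference of 2.12 points with an SE of 2.12, which leaves it undecided. By drug the difference was 3.47 (SE 4.05), 0.39 (SE 3.54) and -0.33 points (SE 3.45) for novobiocin, rifampicin and tetracycline. The summed value also mixes drugs whose shares for genes with equal directions differed, at 14.4%, 25.6% and 26.2%. A change in RNA decay or in the use of internal starts, which the design does not separate, stays untested.

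The rifampicin gene calls in total RNA stood beside ssrA and ssrS shares far above control. A few genes taking most of the counts would lower all others together with library totals as the scaling. Alone they could not give the 41.1% of called genes that were higher. A part for them stays open. Genes that rose strongly, 1034 of them at least 2-fold with TMM, can stay higher under such a shift. The median of all genes was -0.19 with library totals, against 0.02 with TMM. The calls did not rest on the rifampicin library of the highest ssrA share, replicate 3, since 2881 genes passed without it, 2732 of them shared. This count cannot tell whether that library stands apart from the others. Chi-square per degree of freedom was 558 between replicates 2 and 3, against 157 for 1 and 2 and 174 for 1 and 3. Stable RNAs that outlast messenger RNA when transcription starts are blocked may explain the shares, but this stays open, since the tRNA share was 1.78 times that of control with an exact permutation p of 0.1, the smallest the design allows. The rRNA share was 0.648 times that of control (exact permutation p = 0.3). It was only 0.00157% of control and 0.00101% of rifampicin counts, too little to weigh the explanation. The ssrA share was below control in enriched (0.0837% against 0.297%) and non-enriched libraries (0.559% against 0.829%), as was the ssrS share (1.27% against 3.44%, and 0.211% against 0.977%). The tRNA share was above control in both, at 2.46% against 0.496% and 0.741% against 0.307% (exact permutation p = 0.1 each). These libraries were prepared otherwise than total RNA, and the enriched ones capture starts of primary transcripts. Shares there, lower or higher, therefore do not decide whether older RNA lasted. The mean tRNA share was also above control under tetracycline, which does not block transcription starts, at 2.59% against 0.324%.

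The iron uptake list fell under all 3 drugs in total RNA by the preset set test (adjusted p = 0.336, 0.525 and 0.708 with an estimated correlation), while in enriched and non-enriched libraries it passed under novobiocin (adjusted p = 0.288 and 0.317 with an estimated correlation) but not under rifampicin (adjusted p = 0.583 and 0.236) or tetracycline (0.383 and 0.191). In total RNA its summed level was 831 ± 169 CPM in control, 131 ± 32.1 in novobiocin, 208 ± 16.6 in rifampicin and 203 ± 18.8 in tetracycline libraries (SD, n = 3). A shift of the control libraries alone could not give the median difference of -1.18 between novobiocin and rifampicin (SD 0.93 over 17 genes, 11 lower and 2 higher past the test), but novobiocin minus tetracycline was -0.68, with 7 lower past the test, and rifampicin minus tetracycline 0.04, so it stays open as a part. One control library was argued against, since the highest median with any left out was -1.52. Untreated cultures that grew on during the exposure could also give a list lower under 3 drugs, and no control taken before exposure was analysed here.

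Other splits of a comparison, of 6 cultures or, for enriched against non-enriched libraries, of 6 libraries from 3 control cultures, were too few to reach a share under 0.05, since 3 against 3 make 10 splits. In each of the 13 comparisons 1 of 10 splits, the real one, gave as many genes. By edgeR the highest of the other splits gave 0 genes in 12 comparisons and 3 in enriched against non-enriched libraries. At an unadjusted p under 0.05 the highest other splits gave 253, 422 and 74 genes in total RNA, 315, 403 and 322 in enriched libraries and 366, 519 and 154 in non-enriched ones, for novobiocin, rifampicin and tetracycline, against real counts of 2624 to 3049, 1407 to 1516 and 2154 to 2527 past the adjusted test. They gave 182, 253 and 186 genes in the tests of the difference and 522 in enriched against non-enriched libraries. Of the splits of the latter 4, the real one included, part all 3 pairs of libraries from one culture, and the highest of the others among them gave 0 genes by the adjusted test.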

How the results depend on the processing

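Removal of noncoding RNA genes was chosen after the data were seen, and the other alternatives in this part were fixed earlier. Of 242 alternatives to 20 comparison results, 229 left the result on its side and within range, 13 moved it and 0 reversed it. For comparisons of groups the result was the number of genes past the test, which has no sign to reverse. Neither the balance of directions nor the identity of the genes was scored. Library totals were not among the alternatives for the tests of the difference or for enriched against non-enriched libraries. Tetracycline in enriched libraries counted as unmoved with library totals, though 1843 genes passed, 1022 of the 1516 were shared and 87.0% were higher, against 51.6%. Of 14289 alternatives to 1015 single-gene results, 13518 kept the call, 282 lost it, 489 gained it and 0 reversed it. Of 156 list results in total RNA and enriched libraries, 42 were calls, all of them lost with an estimated correlation, and 114 were no calls and stayed so. The replicate block gave 2617, 2935 and 3045 genes in total RNA, 1428, 1447 and 1558 in enriched and 2147, 2217 and 2532 in non-enriched libraries, 1129, 1554 and 1771 in the tests of the difference and 2875 for enriched against non-enriched libraries, and changed no list call in 156. Leaving out 1 replicate gave 2377 to 2540, 2726 to 2920 and 2830 to 2944 genes in total RNA and 1064 to 1341, 1106 to 1308 and 1124 to 1450 in enriched libraries. Correlations of fold changes ranged from 0.400 to 0.447 under novobiocin, 0.354 to 0.384 under rifampicin and 0.402 to 0.427 under tetracycline with 1 culture left out. At 10 CPM or more they were 0.601, 0.499 and 0.509, and Spearman's rho was 0.363 for rifampicin and 0.383 for tetracycline. Correlations of levels at that minimum were 0.221 in control, 0.231 in novobiocin, 0.224 in rifampicin and 0.224 in tetracycline cultures, and Spearman's rho was 0.453 in tetracycline cultures. The cause of these shifts was not tested. The spread between replicates limits the enriched libraries, where few 2-fold changes were recovered in simulated data.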

Other observations

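No test in this part was planned; the overlap of drugs was computed after the single comparisons were seen. In total RNA 309 genes were higher and 447 lower under all 3 drugs, where independent lists would give 157.3 and 162.5, and these numbers leave out the shared controls, so the excess is not read as a shared effect. Lower under all 3 drugs were dsdX (-7.44, -5.35 and -5.34 under novobiocin, rifampicin and tetracycline), the dihydroxyacetone kinase gene dhaK (-4.40, -3.38 and -4.23) and fhuA (-3.65, -3.18 and -3.39). Higher under all 3 were yigI (2.66, 3.96 and 3.18), arnB (5.64, 3.14 and 2.49) and iscR (2.88, 1.84 and 2.30), the regulator of iron-sulfur cluster genes. These genes were chosen after their values were seen.

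Fold changes of pairs of drugs in total RNA had a Pearson r across 4285 genes of 0.328 for novobiocin and rifampicin, 0.282 for novobiocin and tetracycline and 0.529 for rifampicin and tetracycline. Unchanged groups simulated against the same controls gave 0.464, 0.503 and 0.506 in 20 simulations. The simulated r hold no drug effects in their spread, so their size is not comparable with that of the measured r. The covariances were 0.645, 0.612 and 1.22, against simulated covariances of 0.049 for each pair. Higher and lower under both drugs were 512 and 666 genes for novobiocin and rifampicin (432 and 467 for independent lists), 559 and 648 for novobiocin and tetracycline (468 and 465) and 786 and 900 for rifampicin and tetracycline (524 and 521). Genes with opposite calls numbered 385 and 273, 402 and 320, and 262 and 208 in the same order. The numbers for independent lists leave out the shared controls, so the excess is not read as a shared effect.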
